A study of Rattus norvegicus with 6 samples.

How the data were processed

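Lung RNA from 6 rats with MCT-induced PAH was sequenced, 3 after a sham operation (PAH_sham) and 3 after transection of the cervical sympathetic trunk (PAH_TCST), with groups and replicate numbers taken from the sample titles. Per the labels' protocols, messenger RNA was captured on beads and strand-specific libraries, made with dUTP in the second strand, were read from both ends. The deposited values are FPKM (fragments per kilobase of gene, scaled to the mapped fragments of each library), 1 column per sample, which the authors rounded to 2 decimals. HISAT2, without a version, and the build GRCh38 are named in the submitters' processing notes. GRCh38 is a human build while the gene identifiers in the file are rat Ensembl genes, so the build used is uncertain; the counter, the annotation release and any filter are not given in the sources used here. Chromosomes are printed as the file gives them, with no positions. Whether reads shared between near-identical genes were split or dropped is not given either, so values of immunoglobulin, cytochrome P450, glutathione transferase and RT1 genes are uncertain in this respect.

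FPKM hide the number of reads, and rounding keeps whole reads from being recovered for most genes. Relative depth was read from short RNA genes, whose values between 0.2 and 1.5 FPKM lie on steps of single reads. FPKM sums ranged from 445335 to 473836. No interval that needs a read count is given, and the planned count-model alternative was not run because no counts could be had. The 6 libraries all differed from one another, and none was treated as a repeat of another.

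Genes with a mean FPKM of at least 1 over the 6 samples were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), two-sided, with an intensity trend in the moderated variance and Benjamini-Hochberg adjustment over 11806 genes. The pseudocount of 1 understates the change of low genes. No covariate was used, and no further scaling was applied in the main fit. The fit was tested on simulated values for these 11806 genes with 200 genes changed: over 5 runs it found 89.4% of genes changed by 1 and 97.4% of genes changed by 2 on the log2 scale, with 10.2 false calls per run on average. Values were drawn as independent normal values with the moderated variances of the fit. The changed genes were taken from those with a mean log2 value above 2. Real genes are correlated and vary more freely, so these shares do not give the power in the real data. A simulated list shifted by 0.5 was found by camera in 5 of 5 runs, and 0 of 165 unshifted lists of independent genes were called; real genes of a list are correlated, which that simulation leaves out.

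34 gene lists (836 genes) were fixed before the data were examined, for calcium, adrenergic, vasoactive, remodelling and inflammatory genes, for general responses and for cell types that a piece of lung can hold. Of these genes 800 were found, 7 of them through synonyms in the RefSeq gene table of the GRCr8 assembly, used for names only. Lists with at least 5 tested members were compared with the other genes by limma's camera with an inter-gene correlation of 0.01, adjusted over 33 lists, and again with an estimated correlation; fry was run beside it. Genes named in the text follow a rule fixed at the same time: 12 genes per direction with an official symbol and groups that do not overlap, taking those past the threshold by fold change first and filling the rest by smallest p, then up to 4 members per list by smallest p, then 19 genes of adrenergic, calcium, inflammatory and muscle function whatever their value.

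Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, rescaling of each library to the same sum, robust moderation, sample weights, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation, and calcium lists without muscle markers, which removed 0 tested genes and so tested nothing. Added after the data were examined were a cell cycle list without Aurkb and lists of immunoglobulin variable genes and motile cilium genes.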

Results

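RNA from rat lung was sequenced 28 days after an injection of monocrotaline (MCT), a plant alkaloid that damages the lung endothelium and is used to induce pulmonary arterial hypertension (PAH) in rats. All animals were adult male Sprague-Dawley rats. In the PAH_TCST group the cervical sympathetic trunk, which carries sympathetic fibres through the neck, had been cut, and the PAH_sham group had a sham operation. Each group held 3 samples, which the series' design text describes as biological replicates, so every value has n = 3 per group. Sequencing of animals without MCT was not analysed here, so each comparison is between the 2 operated MCT groups. The deposited table gives FPKM (fragments per kilobase of gene, scaled to the mapped fragments of each library) for 20705 genes, of which 11806 had a mean FPKM of at least 1 and were tested. The number of reads per library is unknown. Steps of single reads in short RNA genes gave depths relative to PAH_sham 1 of 1.26 for PAH_sham 2 and 3, 1.19 for PAH_TCST 1, 0.977 for PAH_TCST 2 and 1.03 for PAH_TCST 3. Across genes, the log2 values of library pairs correlated at 0.972 to 0.99 within the groups and at 0.946 to 0.981 between them; genes are not independent replicates.

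The main comparison asked which lung genes differ after transection in animals with PAH. 1 gene rose and 1 gene fell past the threshold (limma, Benjamini-Hochberg adjusted p under 0.05). Cyp4f5 (ENSRNOG00000042496, chromosome 7), a cytochrome P450 of the family that hydroxylates fatty acids and eicosanoids, rose from 2.57 ± 0.214 FPKM (SD, n = 3) in PAH_sham to 5.88 ± 0.151 in PAH_TCST. Its log2 fold change on log2(FPKM + 1) was 0.95 with an SE of 0.0752 and an adjusted p of 0.0403. ENSRNOG00000068649, a protein-coding gene on chromosome 4 with neither a symbol nor a description in the file, fell from 125 ± 18.0 to 29.0 ± 2.87 FPKM, with a log2 fold change of -2.07, an SE of 0.134 and an adjusted p of 0.0219. This second gene carries no official symbol, so it was named after its values were seen. Cyp4f5 passed without PAH_sham 3 but lost its call when any one of the other 5 libraries was left out (highest adjusted p 0.315). ENSRNOG00000068649 lost its call without PAH_sham 2 (adjusted p 0.315) or PAH_TCST 2 (adjusted p 0.073).

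The genes next in order did not pass. Among those with higher values in PAH_TCST, Selenop, the plasma selenium carrier, measured 186 ± 10.8 FPKM in PAH_sham and 361 ± 5.37 in PAH_TCST (limma, adjusted p 0.076). The mitochondrial adenylate kinase gene Ak3 measured 46.9 ± 1.82 and 82.3 ± 2.83, and Pdia5, a protein disulfide isomerase, 13.3 ± 1.15 and 26.5 ± 2.39 FPKM. Lmo2, Cytl1, Nr1d1, Nr1d2, Tef, Hpgd, Wif1 and Kitlg filled the remaining places, with log2 fold changes of 0.56 (Kitlg) to 1.26 (Nr1d1) and adjusted p of 0.0975 or 0.105. On the lower side, Slpi, a protease inhibitor of mucosal secretions, measured 175 ± 72.4 FPKM in PAH_sham and 22.8 ± 3.80 in PAH_TCST (log2 fold change -2.82, SE 0.287, adjusted p 0.0795). Aurkb, a mitotic kinase, measured 81.2 ± 28.8 and 22.8 ± 4.40 FPKM, and Cd300le, a receptor of myeloid cells, 63.7 ± 7.88 and 28.1 ± 6.12. Cabcoco1, Steap1, Cfap100, Tymp, Asgr1, Igkvl-ps19, Tp53inp1, Map3k7cl and Plppr3 completed the lower genes, from -0.63 (Cfap100) to -2.03 (Igkvl-ps19) on the log2 scale.

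**Figure D1:**
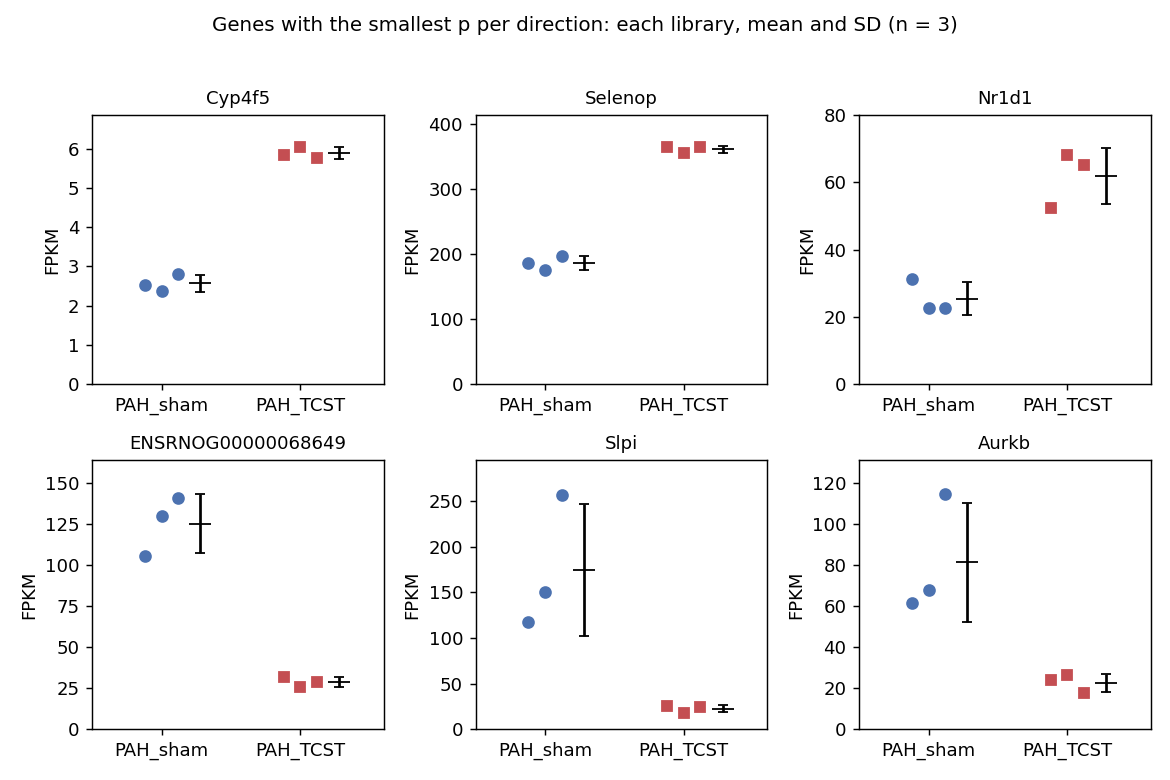
FPKM (vertical axes, from 0) of 3 genes with higher and 3 genes with lower values in PAH_TCST; circles are PAH_sham libraries, squares PAH_TCST libraries, and the black marks give the mean and SD (n = 3). Cyp4f5 lies at 2.57 against 5.88 FPKM on average and ENSRNOG00000068649 at 125 against 29.0, while the other 4 genes did not pass the threshold. Despite the title, Nr1d1 and Aurkb are not among the smallest p of their direction. The unadjusted limma p was 0.00014 for Nr1d1 but 2.57e-05 for Ak3, and 0.000308 for Aurkb but 7.32e-05 for Cabcoco1.

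At an unadjusted p under 0.05, limma gave 2479 genes with higher and 798 with lower values in PAH_TCST, so 75.6% were higher. Median-of-ratios scaling gave 1253 and 1242 genes, or 50.2% higher. This split followed a shift of all genes: the median log2 fold change over tested genes was 0.12 as deposited and 0.02 after that scaling. Camera sets gene lists against the other genes. The medians and counts of higher values given for lists below are taken from 0 and so include this shift. Less that 0.12, list medians were 0.05 for calcium-dependent signalling, 0.069 for adrenergic, 0.084 for innate immune and 0.076 for cytokine genes. Other lists kept larger distances, such as 0.531 for interferon-stimulated and -0.887 for B and plasma cell genes. As deposited, and so with that shift, the groups did not overlap for 3472 genes with higher and 881 with lower values. Together these were 36.9% of tested genes. Chance gives 10% on average, but genes are correlated and a single split can lie far from it, so this share is no test. The counts past the adjusted threshold moved with single libraries: 9 higher and 7 lower genes without PAH_sham 3, 0 and 0 without PAH_sham 2 (1214 and 606 at an unadjusted p), and 0 higher and 6 lower without PAH_TCST 3.

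Of 34 lists fixed before the data were examined, 33 had enough tested members. By limma's camera with a preset inter-gene correlation of 0.01, 5 lists were higher and 5 lower in PAH_TCST relative to the other tested genes. With an estimated correlation 0 lists passed, with an adjusted p of 0.844 for the B and plasma cell list and 0.911 for every other list. By fry, which tests a list without comparing it with other genes, 0 lists moved in one direction and 18 changed in either direction. Over all genes 0 members of any list passed the threshold. Counts adjusted over the list alone are given with each list that had any, and were 0 for the others.

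**Figure D2:**
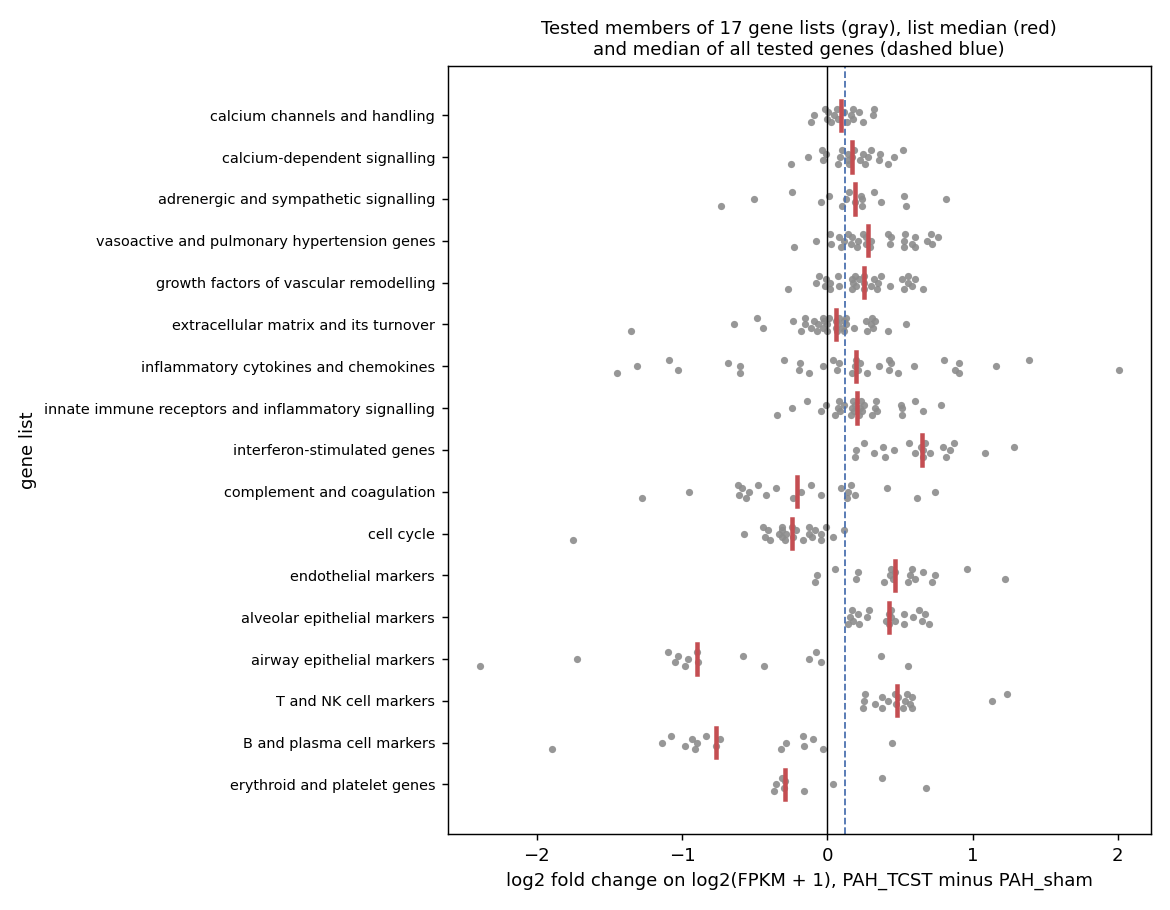
Log2 fold change (horizontal axis, PAH_TCST minus PAH_sham on log2(FPKM + 1)) of each tested member (gray points) of the 8 lists tied to the study's questions and the 9 further lists past the camera threshold at the preset correlation; red bars are list medians and the dashed line is the median of all tested genes, 0.12. The B and plasma cell list has a median of -0.77 and the airway list of -0.89, while the list of calcium channels lies at 0.09.

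Calcium signalling was among the study's stated questions, and no calcium gene passed the test over all genes. Of 18 tested channel and handling genes, 14 had higher and 4 lower values. Their median log2 fold change was 0.09 as deposited, ran from 0.06 without PAH_sham 2 to 0.14 without PAH_sham 1, and turned to -0.002 after median-of-ratios scaling (camera adjusted p 0.768). Orai1 and Stim1, the pore and the sensor of store-operated calcium entry, measured 49.7 ± 4.57 and 10.9 ± 1.16 FPKM in PAH_sham and 62.0 ± 3.95 and 13.9 ± 1.91 in PAH_TCST. The mitochondrial uniporter gene Mcu measured 10.5 ± 1.01 and 12.4 ± 0.394, and the plasma membrane pump gene Atp2b1 2.56 ± 0.460 and 3.21 ± 0.156. Atp2a2, the reticulum calcium pump, measured 22.8 ± 1.69 and 21.0 ± 1.26 FPKM (adjusted p 0.403). Cacna1c, the pore of the L-type channel, was at 0.547 ± 0.0493 and 0.650 ± 0.0721, and Ryr2 was at 0.0133 ± 0.00577 and 0.01 ± 0, both below the filter. Of 23 tested genes of calcium-dependent signalling, 18 had higher values (median 0.17, adjusted p 0.152). In that list 4 genes passed when adjusted over the list alone and 0 over all genes: Camk2g measured 10.3 ± 0.692 and 14.6 ± 1.67 FPKM, Plcd1 9.57 ± 1.15 and 13.1 ± 0.593, Ppp3ca 1.88 ± 0.240 and 2.71 ± 0.116, and Plcb3 7.97 ± 0.460 and 9.89 ± 0.320. Transcripts of heart muscle were present in replicate 3 of both groups: Myh6, a cardiac myosin heavy chain gene, was at 0, 0 and 1.66 FPKM in PAH_sham 1 to 3 and at 0, 0.01 and 2.24 in PAH_TCST 1 to 3. The list of cardiac muscle markers had a median of -0.11 over 11 tested genes (adjusted p 0.129).

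The adrenergic and sympathetic list held 17 tested genes, 13 with higher and 4 with lower values (median 0.19, camera adjusted p 0.852). Over all genes 0 passed, and adjusted over the list alone 1 was higher and 1 lower. Maob, which degrades monoamines, measured 5.57 ± 1.37 FPKM in PAH_sham and 10.5 ± 1.33 in PAH_TCST. The receptor gene Adra1d measured 1.64 ± 0.339 and 0.857 ± 0.187. Both beta receptor genes had higher means in PAH_TCST, Adrb1 with 5.72 ± 2.04 and 8.53 ± 1.79 FPKM (adjusted p 0.201) and Adrb2 with 13.1 ± 2.62 and 19.4 ± 2.56 (adjusted p 0.122). The receptor kinase gene Grk5 measured 13.2 ± 1.96 and 17.3 ± 1.40. Adra1b measured 3.98 ± 0.968 and 3.80 ± 0.465, and the sign of its log2 fold change turned without PAH_sham 1 or PAH_TCST 3. Adra1a, at 0.5 ± 0.25 and 0.637 ± 0.101, lay below the filter. Th and Dbh, enzymes of noradrenaline synthesis, were near 0 in both groups, with Th at 0.0433 ± 0.0322 and 0.0133 ± 0.0116 FPKM and Dbh at 0.0233 ± 0.0322 and 0.02 ± 0.0173. Npy, a cotransmitter of sympathetic nerves, measured 24.3 ± 8.35 and 31.9 ± 16.1 FPKM, and its difference changed sign without PAH_TCST 3.

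**Figure D3:**
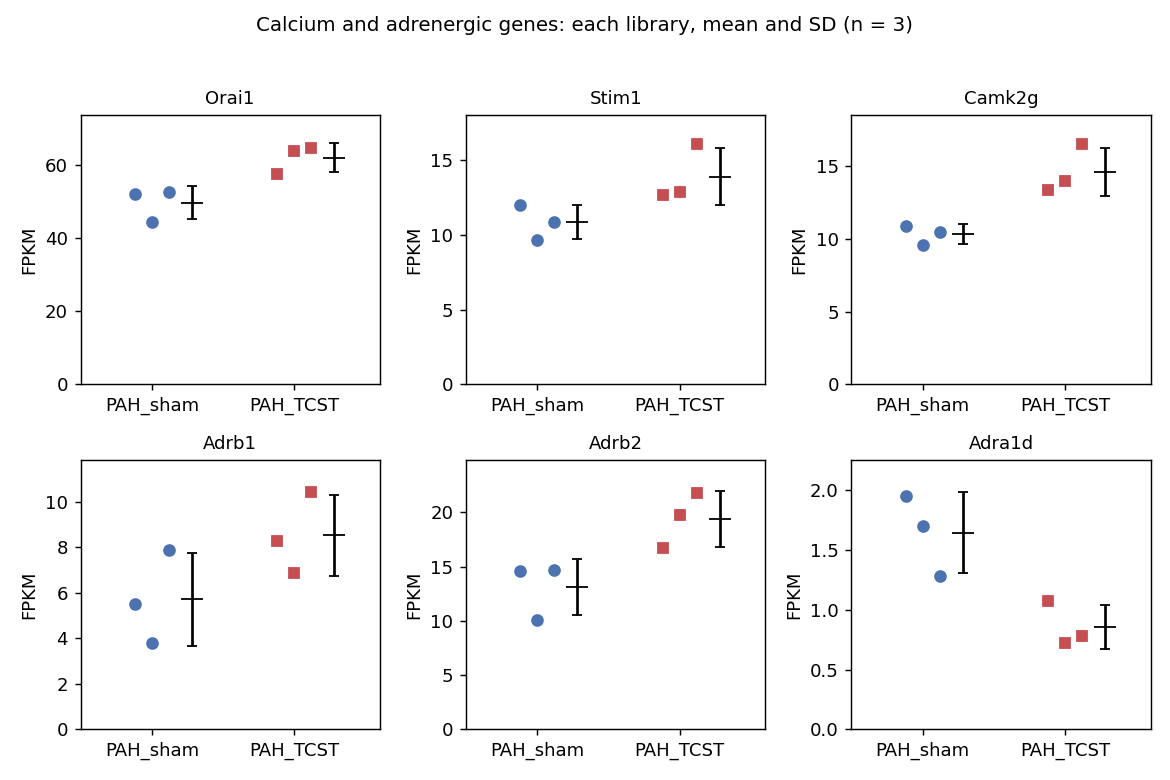
FPKM (vertical axes, from 0) of 3 calcium signalling genes and 3 adrenergic receptor genes; circles are PAH_sham libraries, squares PAH_TCST libraries, and the black marks give the mean and SD (n = 3). Orai1 averages 49.7 against 62.0 FPKM and Adra1d 1.64 against 0.857, and none of the 6 genes passed the threshold over all genes.

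Vasoactive and pulmonary hypertension genes had higher values in 28 of 30 tested members (median 0.28, camera adjusted p 0.048), and the adjusted p was 0.911 with an estimated correlation. Aplnr, the apelin receptor, measured 39.8 ± 4.68 FPKM in PAH_sham and 67.1 ± 15.8 in PAH_TCST, Ece1, which processes endothelin, 58.1 ± 7.93 and 89.6 ± 20.1, and the prostacyclin receptor Ptgir 1.69 ± 0.241 and 2.60 ± 0.416. Tbx4 measured 20.2 ± 4.49 and 29.3 ± 2.41, Edn1 16.6 ± 4.58 and 25.6 ± 7.25 (adjusted p 0.192) and Bmpr2 1.36 ± 0.298 and 1.66 ± 0.361 (adjusted p 0.403). 0 members passed over all genes or when adjusted over the list alone. The list lost its call without PAH_sham 2 (adjusted p 0.0842), PAH_sham 3 (0.148) or PAH_TCST 3 (0.101). Aplnr, Apln, Eng and Ednrb also belong to the list of endothelial markers, so the results of the vasoactive and endothelial lists are not fully separate.

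For vascular remodelling, 26 of 31 tested growth factor genes had higher values (median 0.25, camera adjusted p 0.129), and the list passed without PAH_sham 1 (adjusted p 0.0234) or PAH_TCST 3 (0.0312), while without PAH_sham 2 the median was 0.16 (0.237). Hey2 and Notch1, of the Notch pathway, measured 1.09 ± 0.2 and 8.03 ± 0.636 FPKM in PAH_sham and 1.82 ± 0.150 and 12 ± 2.2 in PAH_TCST. Kdr, the main receptor for vascular endothelial growth factor, measured 20.1 ± 3.63 and 32.5 ± 7.59, and Angpt1 1.37 ± 0.102 and 1.82 ± 0.0851. The extracellular matrix list was split, with 21 of 37 values higher. Its median was 0.06, while its mean and the camera direction lay below 0 (adjusted p 0.199), and the median turned to -0.06 after median-of-ratios scaling. Without PAH_TCST 1 the list passed as lower (median -0.06, adjusted p 0.00467). Sparc measured 1245 ± 162 and 1655 ± 38.1 FPKM, Col5a2 18.1 ± 1.37 and 22.9 ± 1.26, Timp2 23.0 ± 2.20 and 28.5 ± 1.045, and Col15a1 18.5 ± 5.03 and 27.2 ± 5.89. Smooth muscle contractile genes stood at a median of 0.01, which turned to -0.10 after median-of-ratios scaling and -0.06 after quantile normalization (adjusted p 0.0676). Actg2 measured 109 ± 12.5 and 84.0 ± 4.60, Des 59.1 ± 5.6 and 47.8 ± 2.34, Cnn1 50.1 ± 1.24 and 41.3 ± 4.38, and Acta2, the smooth muscle actin, 271 ± 25.6 and 233 ± 22.8 FPKM (adjusted p 0.269). Synm, an intermediate filament gene, went the other way, with 4.07 ± 0.632 and 6.21 ± 1.17.

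Endothelial markers were higher in 17 of 19 tested members (median 0.47, camera adjusted p 0.0103), and the adjusted p was 0.911 with an estimated correlation. Adjusted over the list alone, 10 passed as higher and 0 as lower; 0 passed over all genes. Vwf, the von Willebrand factor, measured 41.6 ± 5.55 FPKM in PAH_sham and 69.7 ± 2.61 in PAH_TCST. Relative to the mean of the 6 libraries, the list medians were 0.13, 0.11 and 0.58 in PAH_TCST 1 to 3 and -0.14, -0.47 and -0.19 in PAH_sham 1 to 3, and without single libraries the difference ran from 0.37 to 0.67. Plvap, another member of the list, measured 209 ± 45.2 and 504 ± 197 (409.05, 372.19 and 730.67 in PAH_TCST 1 to 3). The lymphatic marker Lyve1, typed as a pseudogene in the file, measured 9.61 ± 0.784 and 20.1 ± 5.57. Alveolar epithelial markers had higher values in 21 of 21 members (median 0.42, adjusted p 0.00776), again with an adjusted p of 0.911 with an estimated correlation, and the call was lost without PAH_sham 3 (adjusted p 0.0529). Rtkn2, a marker of flat type I cells, measured 3.76 ± 0.916 and 6.68 ± 0.968, Akap5 8.12 ± 1.73 and 13.3 ± 2.72, Etv5 14.3 ± 2.09 and 19.7 ± 2.10, and Nkx2-1 87.7 ± 9.96 and 117 ± 14.5 FPKM. The fibroblast and pericyte list had a median of 0.21 (adjusted p 0.852), with Dpt at 126 ± 13.6 and 170 ± 8.36 and Npnt at 58.4 ± 9.57 and 84.0 ± 7.68 FPKM.

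Inflammatory cytokines and chemokines went both ways, with 22 higher and 12 lower values among 34. Their median was 0.20, or 0.10 without PAH_TCST 1, while camera placed the list below the other genes (adjusted p 0.768). Csf1 and Csf2 passed as higher when adjusted over the list alone and 0 genes passed over all genes: Csf1, the macrophage growth factor, measured 10.96 ± 0.771 FPKM in PAH_sham and 15.8 ± 1.09 in PAH_TCST, and Csf2 4.59 ± 0.437 and 6.50 ± 0.496. Il33 measured 9.44 ± 1.14 and 14.9 ± 2.59 and Ccl2, which attracts monocytes, 11.4 ± 5.50 and 21.0 ± 2.70 (adjusted p 0.127). Cxcl13, which attracts B cells, measured 51.6 ± 17.7 and 20.2 ± 8.04. Il1b (10.6 ± 1.88 and 12.3 ± 0.725 FPKM, adjusted p 0.309) and Tnf (3.19 ± 1.15 and 3.70 ± 0.272, adjusted p 0.479) overlapped between the groups, and Il6, at 0.287 ± 0.0907 and 0.227 ± 0.101, lay below the filter. Innate immune genes had higher values in 25 of 30 members (median 0.20, adjusted p 0.148). Icam1 measured 147 ± 30.2 and 231 ± 24.5, Tnfrsf1b 10.9 ± 1.67 and 15.9 ± 1.78, Il6r 8.42 ± 0.657 and 12.4 ± 1.68, and Nfkb1 16.0 ± 1.64 and 20.4 ± 0.872 FPKM.

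Interferon-stimulated genes were higher in 20 of 20 tested members (median 0.65, camera adjusted p 0.00529), and the adjusted p was 0.911 with an estimated correlation. Irf1, a transcription factor of the interferon response, measured 40.3 ± 6.65 FPKM in PAH_sham and 70.9 ± 12.7 in PAH_TCST, and the GTPase genes Gbp2 and Gbp5 measured 7.85 ± 2.07 and 3.90 ± 0.822 against 15.2 ± 3.17 and 7.67 ± 1.69. Ifit1 measured 0.340 ± 0.511 and 2.22 ± 0.980. In this list 4 genes passed when adjusted over the list alone and 0 over all genes. The libraries of PAH_TCST differed among themselves, with list medians of 0.31, -0.18 and 0.73 relative to the mean of the 6 libraries. In PAH_sham 1 to 3 the medians were -0.35, -0.50 and -0.12, so PAH_TCST 2 lay below PAH_sham 3. The median difference between groups was 0.34 without PAH_TCST 3. Major histocompatibility class II genes had higher values in 9 of 9 members (median 0.26, adjusted p 0.768), among them RT1-Da at 265 ± 52.6 and 333 ± 99.9 and Ciita at 4.46 ± 1.15 and 6.15 ± 1.84 FPKM. Relative to the mean of the 6 libraries their medians were 0.08, 0.60 and -0.30 in PAH_TCST 1 to 3 and -0.35, -0.18 and 0.11 in PAH_sham 1 to 3, so PAH_TCST 2 was highest and PAH_TCST 3 lay below 2 PAH_sham libraries. With 1 library left out the log2 fold change of RT1-Da ran from 0.08 to 0.51.

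Lymphocyte markers divided. B and plasma cell genes were lower in 16 of 17 tested members (median -0.77, camera adjusted p 1.39e-10), and the adjusted p was 0.844 with an estimated correlation. The joining chain of secreted antibodies, Jchain, measured 2377 ± 415 FPKM in PAH_sham and 1085 ± 216 in PAH_TCST. Ighm measured 3399 ± 1561 and 869 ± 213; the file describes that row as the epsilon heavy chain, so its class is uncertain. Tnfrsf17, a receptor of plasma cells, measured 35.6 ± 6.39 and 18.5 ± 3.36, and Pou2af1, a coactivator in B cells, 48.4 ± 11.3 and 23.7 ± 2.59. Adjusted over the list alone 9 genes passed as lower, and 0 over all genes. T and NK cell genes were higher in 18 of 18 members (median 0.48, adjusted p 0.00255), and the adjusted p was 0.911 with an estimated correlation. Of the 18 genes, 10 passed as higher when adjusted over the list alone and 0 over all genes. Cd247, of the T cell receptor complex, measured 7.53 ± 1.48 and 11.7 ± 0.835 FPKM, the granzyme gene Gzmb 2.35 ± 0.536 and 6.61 ± 2.54, Klrd1 2.47 ± 0.542 and 4.14 ± 0.588, and Cd8b 4.12 ± 0.170 and 6.14 ± 1.20.

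**Figure D4:**
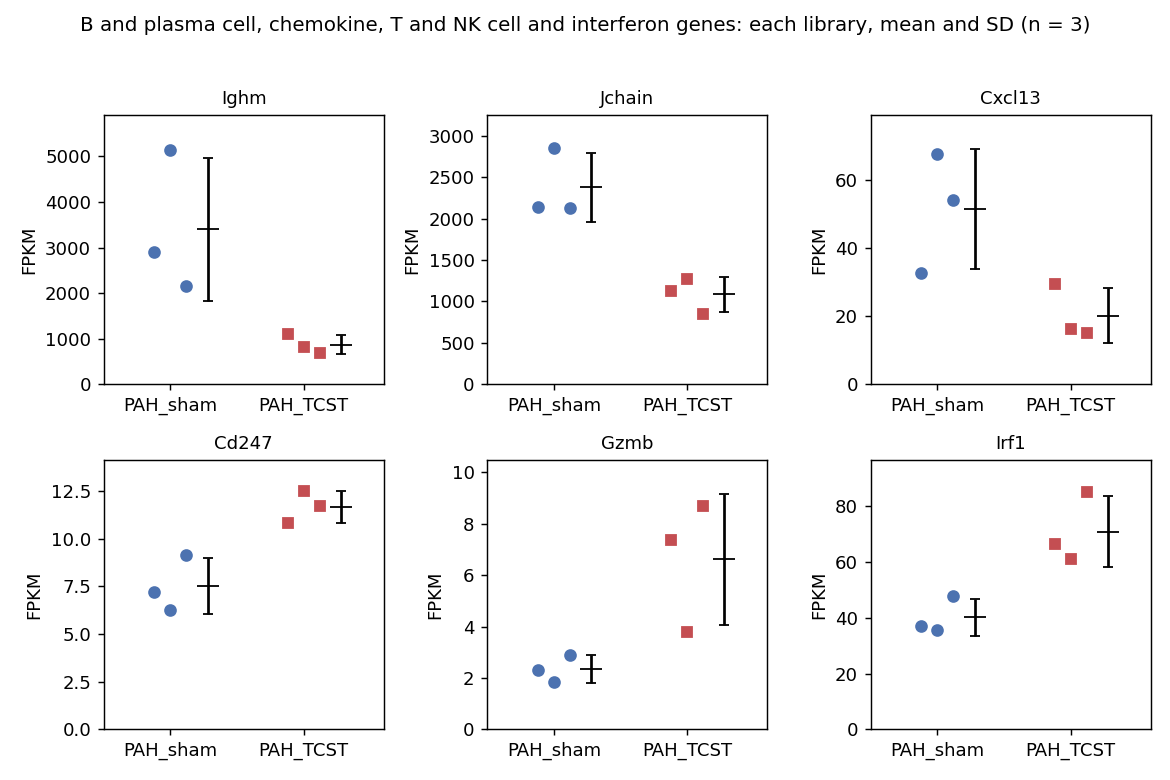
FPKM (vertical axes, from 0) of 2 B and plasma cell genes, the chemokine gene Cxcl13, 2 T and NK cell genes and the interferon-response gene Irf1; circles are PAH_sham libraries, squares PAH_TCST libraries, and the black marks give the mean and SD (n = 3). Jchain averages 2377 against 1085 FPKM and Gzmb 2.35 against 6.61; none of the 6 genes passed the threshold over all genes.

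The macrophage, neutrophil and mast cell lists did not pass. Macrophage and monocyte genes had a median of -0.03 (adjusted p 0.193), with Ly6c at 123 ± 13 and 216 ± 52.0 FPKM and Csf1r at 41.7 ± 2.72 and 54.2 ± 4.26. The neutrophil median was 0.22 with a camera direction below the other genes (adjusted p 0.768), with Ngp at 5.12 ± 1.51 and 11.8 ± 4.73. Mast cell and eosinophil genes stood at -0.02 (adjusted p 0.411), where 1 gene, Kit, passed as higher when adjusted over the list alone; Kit measured 2.60 ± 0.324 and 4.73 ± 0.936 and Mcpt1 34.3 ± 16.1 and 16.4 ± 14.1. Erythroid and platelet genes were lower in 6 of 9 members (median -0.29, adjusted p 0.048), and the adjusted p was 0.911 with an estimated correlation. The members went apart, Itga2b of platelets with 1.6 ± 0.191 and 3.24 ± 1.08 FPKM and Slc4a1 of red cells with 2.31 ± 0.605 and 1.55 ± 0.274. That call was lost in 4 of the 6 runs with 1 library left out, those without PAH_sham 1 (adjusted p 0.175), PAH_sham 3 (0.0529), PAH_TCST 1 (0.18) and PAH_TCST 2 (0.211); the median was -0.16 without PAH_sham 1 and -0.19 without PAH_TCST 2.

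Airway epithelial genes were lower in 14 of 16 tested members (median -0.89, camera adjusted p 8.83e-08), and the adjusted p was 0.911 with an estimated correlation. Of these, 9 passed as lower when adjusted over the list alone and 0 over all genes. The secretory gene Scgb3a1 measured 1206 ± 242 FPKM in PAH_sham and 622 ± 132 in PAH_TCST. Genes of motile cilia followed, with Tekt1 at 14.2 ± 3.18 and 6.75 ± 2.18, Ccdc153 at 64.8 ± 7.94 and 32.1 ± 12.1, and Dnah9 at 1.34 ± 0.0929 and 0.740 ± 0.226 FPKM. PAH_TCST 2 was lowest, and without it the list median was -0.55. Cell cycle genes were lower in 23 of 25 members (median -0.24, adjusted p 4.15e-07), and the adjusted p was 0.911 with an estimated correlation. Adjusted over the list alone 1 gene, Aurkb, passed as lower. Rrm2 measured 4.39 ± 1.14 and 2.63 ± 0.679, Tpx2 3.21 ± 0.807 and 2.37 ± 0.416, and Ccne1 5.51 ± 2.11 and 3.69 ± 0.578 FPKM. The list median of PAH_sham 3 was 0.54 above the mean of the 6 libraries, and without that library the difference between groups was -0.03. Complement and coagulation genes were lower in 14 of 22 members (median -0.21, adjusted p 0.00453), and the adjusted p was 0.911 with an estimated correlation. Cfd and Cfi, complement factors D and I, measured 43.0 ± 7.98 and 9.43 ± 1.5 in PAH_sham and 18.0 ± 6.86 and 4.43 ± 1.11 in PAH_TCST, whereas Vwf and Plau, of haemostasis and fibrinolysis, had higher values. Of the members, 2 passed as higher and 2 as lower when adjusted over the list alone. Without PAH_TCST 3 the median was -0.12.

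The lists of general responses did not pass by camera. Circadian clock genes went both ways (12 of 18 higher, median 0.19, adjusted p 0.553). Adjusted over the list alone 7 passed as higher and 1 as lower, and 0 over all genes; Nr1d1 measured 25.5 ± 4.93 and 61.9 ± 8.42 FPKM, Dbp 13.3 ± 0.958 and 39.5 ± 14.6, and Tef 15.0 ± 1.73 and 29.6 ± 4.33. Xenobiotic metabolism had a median of 0.62 (adjusted p 0.428), with Fmo1 at 20.9 ± 4.36 and 49.7 ± 11.9, Cyp2b1 at 132 ± 31.8 and 286 ± 75.2, and Gstm1 at 70.3 ± 1.6 and 41.3 ± 9.59 FPKM. In that list 4 genes passed as higher and 1 as lower when adjusted over the list alone. Relative to the mean of the 6 libraries its medians were 0.27, -0.12 and 0.78 in PAH_TCST 1 to 3. In PAH_sham 1 to 3 they were -0.03, -0.43 and -0.36, so PAH_TCST 2 lay below PAH_sham 1. Immediate-early genes stood at 0.05, or -0.05 after median-of-ratios scaling (adjusted p 0.768), although the endothelial factor Klf2 measured 19.96 ± 3.13 and 45.1 ± 13.4 and Klf6 7.49 ± 0.795 and 11.8 ± 0.541, with 2 genes past the threshold as higher when adjusted over the list alone. Hypoxia and glycolysis genes stood at 0.08, or -0.03 after that scaling (adjusted p 0.579), with 1 gene lower when adjusted over the list alone, Egln3, at 3.92 ± 0.875 and 1.77 ± 0.139 and Epas1 at 199 ± 31.3 and 341 ± 106 FPKM. Medians were 0.14 for glucocorticoid-responsive genes (adjusted p 0.768), 0.11 for oxidative phosphorylation (0.615) and 0.13 for antioxidant genes (0.852). The camera direction was below the other genes for the glucocorticoid, hypoxia, antioxidant, smooth muscle, neuronal and mesothelial lists although their medians lay above 0, and the means of the smooth muscle and mesothelial lists also lay below 0. Neuronal and Schwann cell genes stood at 0.01 over 6 tested members, 1 higher and 1 lower when adjusted over the list alone (adjusted p 0.768), and mesothelial and adipocyte genes at 0.04 over 9 (0.411); both turned below 0 after median-of-ratios scaling, and the neuronal list also after quantile normalization. The skeletal muscle list had 4 tested members, all with higher values, too few for a list test; 2 of them passed as higher when adjusted over the list alone.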

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

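The list without Aurkb was chosen after the results were seen; the other alternatives were planned. The counts of 1 higher and 1 lower gene held under both pseudocounts, median-of-ratios scaling, rescaling, robust moderation and sample weights. They were 0 and 0 with no filter (2844 and 1314 genes at an unadjusted p). More genes then shared the adjustment and the moderated variance was fitted anew, and their parts were not separated. With a mean FPKM of at least 5, 0 genes were higher, since Cyp4f5 lies under that filter, and quantile normalization gave 2. With 1 library left out the counts ran from 0 to 9 higher and from 0 to 7 lower. Deviations of replicates with the same number correlated at -0.171, 0.0149 and -0.0778, against -0.151 to 0.249 for unlike numbers. That shows no strong shared deviation over all genes but cannot exclude a pairing. The labels do not say what the numbers stand for. With the replicate number as a block 0 higher and 0 lower genes passed, and no list call changed.

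For lists the values are camera's adjusted p. With an estimated correlation all 10 list calls ended, at 0.844 for B and plasma cells and 0.911 for the rest. Correlated members then count for less, and the test also rests on the few degrees of freedom that the samples leave. These parts were not separated. The erythroid list stood at 0.0914 under median-of-ratios scaling, 0.19 under quantile normalization, 0.0536 after rescaling and 0.0573 without a filter, where complement also stood at 0.0573. The vasoactive list stood at 0.0536 after rescaling, 0.129 with a mean FPKM of at least 5 and 0.17 with sample weights. Growth factors passed under median-of-ratios scaling (0.044) and without a filter (0.0133), as did innate immune genes without a filter (0.0393). Lists without a call turned direction: calcium channels with a mean FPKM of at least 5 (0.985) and with sample weights (0.991), and cytokines under median-of-ratios scaling (0.749), no filter (0.602), quantile normalization (0.899) and sample weights (0.991). The cause was not tested for these. The cell cycle call held without Aurkb (4.01e-06). Leaving muscle markers out of the calcium lists removed 0 tested genes, so it tested nothing, though its 2 rows count as kept below.

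With 1 library left out, adjusted p ran from 0.00449 to 0.211 for the erythroid list, 0.0083 to 0.148 for the vasoactive list, 0.000627 to 0.0529 for alveolar markers, 0.0234 to 0.312 for growth factors, 0.00467 to 0.828 for extracellular matrix and 0.046 to 0.471 for innate immune genes. Directions turned for calcium channels (0.527 to 0.963), adrenergic genes (0.669 to 0.987) and cytokines (0.539 to 0.983). Fold changes of Adra1b ran from -0.174 to 0.104 and of Npy from -0.0521 to 0.578. Over all alternatives 249 of the list results kept direction and side of the threshold, 26 lost the call, 7 gained it and 10 turned.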

Other observations

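The tests of scaling, of T and NK cells, of lymphoid chemokines and of club cells, and both lists taken from the file's gene types and descriptions, were chosen after the result was seen; genes outside the naming rule are named after their values were seen. Antibody transcripts beyond the fixed list moved with it. Of 33 tested genes typed as immunoglobulin variable genes, 29 had lower values in PAH_TCST (median log2 fold change -1.32), 15 passed as lower when adjusted over the list alone and 0 over all genes. Camera gave an adjusted p of 7.16e-17 at the preset correlation and an adjusted p of 0.448 with an estimated correlation. These genes held 0.891% to 1.58% of the FPKM sum in the PAH_sham libraries and 0.246% to 0.552% in the PAH_TCST libraries. The gene with the highest mean over the 6 libraries, AABR07060872.1 on chromosome 4, has no description in the file and took 4.54%, 8.56% and 4.5% of the sum in PAH_sham 1 to 3 and 2.48%, 2.16% and 1.42% in PAH_TCST 1 to 3. In each PAH_TCST library Scgb1a1 was higher, with 17292.76, 15580.56 and 20942.56 FPKM against 11277.67, 10057.98 and 6378.01.

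Motile cilium genes, the axonemal dyneins, tektins, radial spoke and cilia-associated proteins named in the file's descriptions, had lower values in 64 of 66 tested members (median -0.70). Of these, 51 passed as lower and 1 as higher when adjusted over the list alone, and 0 over all genes. The adjusted p by camera was 3.34e-37 at the preset correlation and 0.59 with an estimated correlation. That estimate was 0.633, so the members are not separate results. Tekt1, Dnah9, Dnai1, Cfap126 and Rsph1 were also tested in the airway list, so the cilium and airway results are not separate either. Relative to the mean of the 6 libraries, the cilium medians were -0.039, -0.655 and -0.248 in PAH_TCST 1 to 3. In PAH_sham 1 to 3 they were 0.432, 0.405 and 0.174. PAH_TCST 2 was thus lowest, and PAH_TCST 1 lay near the mean. Cfap100 measured 2.71 ± 0.235 FPKM in PAH_sham and 1.40 ± 0.0577 in PAH_TCST (n = 3 each).

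The 6 samples form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 genes past the adjusted threshold, the highest of the other splits gave 5, and 2 of the 10 splits gave at least 2. At an unadjusted p under 0.05 the real split gave 3277 genes and the highest other 674. For lists, the real split gave 10 past the camera threshold at the preset correlation, 9 of the 10 splits gave at least as many and the highest other gave 14. The unadjusted p of the B and plasma cell list was 4.2e-12 in the real split and lower, 4.48e-13, in the split of PAH_sham 1, PAH_TCST 1 and PAH_TCST 2 against the rest.

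Antibody and B cell genes had lower values in PAH_TCST while T and NK cell genes had higher values, called by camera only at the preset correlation: with an estimated correlation the adjusted p was 0.844 for B and plasma cells, 0.911 for T and NK cells and 0.448 for immunoglobulin variable genes, and 0 members passed over all genes. Scaling between samples as the whole cause is argued against by the B and plasma cell median, which was -0.88 after median-of-ratios scaling. A loss of lymphocytes of every kind in the tissue pieces is argued against by the T and NK cell median of 0.48. Fewer lymphoid aggregates remain open: Cxcl13, Ccl19 and Ccl21, chemokines of such aggregates, had a median of -0.68, which is the value of Ccl21 and ran from -1.02 to -0.44 for that gene with 1 library left out. Ccl19 and Ccl21 overlapped between the groups, and only Cxcl13, seen before this test was made, did not. Whether the transection itself may lower antibody-producing cells cannot be told apart from a difference between the tissue pieces that were sequenced.

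Of 10 clock output genes, 7 had higher values in PAH_TCST with no overlap between the groups (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Per3). Per1 and Per2 overlapped, as did Bhlhe41, which had the lower mean in PAH_TCST (13.1 ± 0.692 and 10.8 ± 2.88 FPKM, n = 3 each). A different hour of tissue collection would lower the genes of the opposite phase, and Bmal1, Npas2, Clock, Nfil3 and Cry1 (4 of them tested) had a median of -0.19 as deposited, short of the bound of -0.2 set beforehand, but past it at -0.28 after median-of-ratios scaling, -0.23 after quantile normalization and -0.21 after rescaling to the same sum. The 4 tested genes each overlapped between the groups. Clock, below the filter and so outside that median, went the other way, with 0.75 ± 0.02 and 0.897 ± 0.0737 FPKM and no overlap. That explanation therefore stays open, and no collection times are given in the sources used here. The cervical sympathetic trunk also carries the nerve supply of the pineal gland, so a shifted rhythm after transection may be a biological explanation, which was not tested.

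Cilium genes and Scgb3a1 had lower values in PAH_TCST, but Scgb3a1 did not pass over all genes (adjusted p 0.105), and the cilium list passed by camera only at the preset correlation (adjusted p 0.59 with an estimated one). Club cell markers, of the small airways as well, bear on less airway of every size in the tissue pieces as the whole cause. They overlapped between the groups and were split, with log2 fold changes of 0.56 (SE 0.246) for Scgb1a1, -0.13 (SE 0.275) for Scgb3a2 and 0.37 (SE 0.557) for Cyp2f4. That explanation needs them all to follow the cilium genes at -0.70. Scgb1a1 argues against it, with 0.388 to 0.743 when 1 library was left out. Scgb3a2 and Cyp2f4 are less certain, given their SE. The median of 0.37 is the value of Cyp2f4 and lies 1.07 from -0.70. The SD of 0.355 between the 3 genes does not measure the spread between animals. A part played by less airway is not excluded. A smaller share of large, cartilage-bearing airway stays open: 12 cartilage genes had a median of -0.18 on log2(FPKM + 0.1), between the bounds set beforehand. Most had values near 0 FPKM, where the added 0.1 limits how far a fold change can fall. This median therefore cannot decide the question. Of the 12, 2 were lower without overlap between the groups, Col9a2 and, near the floor, Col2a1, and 10 overlapped. Col9a3, at -0.708, was among those that overlapped. Col9a2 measured 10.5 ± 4.03 and 3.39 ± 0.794 FPKM (n = 3 each), whereas the next most abundant had means of 1.12 and 1.06 (Snorc), 0.95 and 0.79 (Comp) and 0.67 and 0.657 FPKM (Col11a2). An effect of the transection on ciliated cells may equally underlie the pattern and was not tested.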
